A study of Mus musculus with 12 samples.

How the data were processed

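Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase cuts and tags open DNA, in 12 libraries of NIH/3T3 cells, an immortal mouse fibroblast line. The labels put 3 biological replicates in each of 4 groups: wild type (WT), PTC1, PTC2 and LD. PTC1 carries an insertion of 1 nt after position 280 of Actg1 that places a premature stop codon in exon 3. PTC2 carries an insertion of 4036 nt after position 1096 with a premature stop codon in exon 5. LD lacks the full Actg1 locus. Each sample held 25000 cells, lysed with digitonin and transposed for 30 min at 37 °C, and the equimolar pool was sequenced with paired ends on a NextSeq2000. The labels name no separate clones or lines of an allele. The samples were therefore taken as 1 line per allele, and the tests as measuring the spread between samples, not between lines.

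The deposited table gives, for 81995 regions called over all samples, a score per sample. By its values the score is a read count scaled by 1 factor per sample and then rounded to whole numbers by the authors. Whole numbers are missing or doubled in frequency at regular steps in every column, and median-of-ratios factors of the 12 columns lay between 1.008 and 1.014 over the 80509 regions above 0 in every sample. The authors' processing notes name Trimmomatic 0.39, STAR 2.7.10a, Picard 2.25.5, DESeq2 1.30.1 and the mouse genome build mm10, with no role or order. The peak caller and any shift for the Tn5 cut are not given in the sources used here. For regions near a gene, the deposited table also lists the gene, the distance from the region centre to its start site in base pairs, and the fraction of the region inside the gene body. Its largest listed distance is 6159 bp, so most distal regions carry no gene.

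The scale of each column was recovered from the gaps in its whole numbers, which gives an estimate of the reads in regions per library. Those estimates run from 25.01 to 44.97 M (mega). The variance between replicates was 2.41 to 4.09 times the counting noise at these depths. That ratio is a summary per pair of libraries and was not taken for regions with low values on their own. Intervals printed for log2 changes are 95% intervals of the fit and cover the spread between these libraries.

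Before the data were examined, the comparisons, the tests, the gene lists, the rule for named genes and the alternatives were fixed. The planned test for raw counts was replaced by the planned fallback for normalized values, because the table holds scaled values. Log2 of the value plus 1 was fitted with limma 3.58.1 in R 4.3.3 (a mean per group over all 12 libraries, empirical Bayes with a trend). The 81985 regions with a mean of 5 or more were tested and 10 were left out. Regions with a Benjamini-Hochberg adjusted p under 0.05 over all regions tested were called. The comparisons were each mutant with WT, the mean of PTC1 and PTC2 with LD, and PTC1 with PTC2. Regions shared by the premature stop lines were those called in both against WT in 1 direction and called in that direction in the mean of both against LD. The fit was tested on simulated libraries drawn around the mean of each region over all samples, with known changes put into the PTC1 group. Against WT it recovered 20% of 50 regions at a log2 change of 0.5, 88% at 1 and 100% at 2 and 3. So few changed regions make the adjusted threshold stricter than in the real data, where many regions were called. With a large part of the regions changed, 1.781% of the calls were false.

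Named regions were all actin family regions (annotated to Actg1, Actb, Acta1, Acta2, Actc1 or Actg2, or within 10000 bp of these genes) and, per comparison, the 10 largest rises and the 10 largest falls among called regions. Those had all 3 mutant libraries beyond all 3 WT libraries, a mean of at least 20 in the higher group and a gene with a proper symbol, with 1 region per gene and 1 per 100000 bp. For the regions shared by both premature stop lines the rule did not say how to rank. The smallest of the 3 changes was used, a choice made after the values were seen. In the comparisons with LD, 1 gene that the rule selects is not reported here. For each gene list, up to 4 members with the lowest adjusted p were eligible to be named.

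The 20 lists hold 441 genes from textbook knowledge: actin family, actin-binding and remodelling, MRTF-SRF contractile targets, immediate early genes, YAP-TEAD targets, nonsense-mediated decay, mRNA decay machinery, COMPASS complexes, fibroblast and matrix, p53 targets, interferon response, cell cycle, housekeeping, and markers of skeletal and cardiac muscle, adipocytes, chondrocytes and osteoblasts, epithelium, endothelium, blood and neural cells. Each gene was read at the region nearest its start site. Lists were tested with camera in limma at a preset correlation of 0.01 and with an estimated correlation, over 12337 genes with a tested region.

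Alternatives were scaling to the same median, loess normalization, no low filter, a mean of 50 or more, pseudocounts of 0.5 and 10, the fit on only the groups compared, replicate number as a block, a log2 change of 1 or more, centring each chromosome, and leaving out each library. Subtracting the running median of 101 neighbouring regions (local centring), camera after either centring, and counting shared regions for the other pairings of mutant lines were chosen after seeing the data. Tests made for raw counts and other size factors for the counts of regions were not run, since the values are already scaled. Raw reads were not used here.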

Results

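Accessibility was compared between NIH/3T3 fibroblasts with an intact Actg1 gene, which encodes cytoplasmic gamma-actin, and 3 mutant lines. PTC1 and PTC2 carry premature stop codons, so their Actg1 mRNA is open to nonsense-mediated decay, and LD lacks the locus and makes no Actg1 mRNA. The series asks what mRNA degradation contributes to transcriptional adaptation, in which decay of a mutant mRNA is followed by higher output of related genes. Each group had 3 libraries. The normalized read counts of a library summed to 33.61 to 34.02 M (mega) in WT, 32.74 to 33.58 M in PTC1, 33.57 to 34.8 M in PTC2 and 31.29 to 32.41 M in LD. Estimated reads in regions were 30.35 to 32.91 M in WT, 30.32 to 35.14 M in PTC1, 35.81 to 44.97 M in PTC2 and 25.01 to 33.33 M in LD. The regions covered 20 chromosomes with a median width of 522 bp and a median normalized read count of 125. Of all regions, 25045 (30.5%) were listed with a gene. Libraries of a group correlated with Pearson's r of 0.982 to 0.987 across regions, which are not independent replicates, and libraries of different groups with 0.817 to 0.933. On the first principal component (47.2% of the variance) PTC1 lay at 223 to 229.9 and LD at -139.4 to -129.7. On the second (28.3%) PTC2 stood apart at -181.2 to -171.9.

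The question of related genes starts with the other actins. The region at the start site of Actg2, the smooth muscle gamma-actin gene, was far more open in both premature stop lines than in WT, and much less so in LD. This region (chromosome 6, 83535961 to 83536888, mm10, centre 160 bp from the start site) had a normalized read count of 27 ± 10.1 (SD, n = 3) in WT, 404.7 ± 31.8 in PTC1, 341 ± 11.1 in PTC2 and 43 ± 9.85 in LD. The fold over WT was 15.2 in PTC1 (log2 3.93, SE 0.201, limma adjusted p = 3.29e-16) and 12.8 in PTC2 (log2 3.68, SE 0.201, adjusted p = 1.85e-15). In LD it was 1.63 (log2 0.70, adjusted p = 0.00498), and without WT replicate 1 the LD change was 0.38 with an adjusted p of 0.0794. The premature stop lines exceeded LD by 8.59-fold (log2 3.10, SE 0.174, adjusted p = 2.02e-15), and by a log2 of 2.35 after local centring. PTC1 and PTC2 differed by 0.24 (95% interval -0.17 to 0.66, adjusted p = 0.299), and in the fit on only those groups by an adjusted p of 0.0303.

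Inside the Actg2 gene body, a smaller region (83533791 to 83534017) went from 15.67 ± 2.89 in WT to 88.67 ± 9.5 in PTC1 and 80 ± 4.36 in PTC2, with 12 ± 4.58 in LD. Its log2 changes were 2.44, 2.29 and -0.40 (adjusted p = 4.71e-09, 1.67e-08 and 0.218). Upstream of Actg2 (83541748 to 83542936) the value rose from 73 ± 16.5 to 415.7 ± 43.1 in PTC1 and 150.7 ± 18.6 in PTC2, with 75.33 ± 14 in LD. That region differed between PTC1 and PTC2 by 1.46 (adjusted p = 6.62e-09). Near the 3′ end of Actg2, a region at 83512300 to 83512759 rose by 0.76 in PTC1 and 0.81 in PTC2 and exceeded LD by 0.51. After local centring its changes against WT lost the call (0.27 and 0.42) and the difference from LD turned to -0.24. The start site region of the neighbouring Dguok gene, a mitochondrial nucleoside kinase, was 0.38 higher in PTC1, 0.27 higher in PTC2 and lower in LD (log2 -0.36). Local centring turned the first of these to -0.12 and the second to -0.12, and chromosome centring turned the LD change to 0.005.

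**Figure D1:**
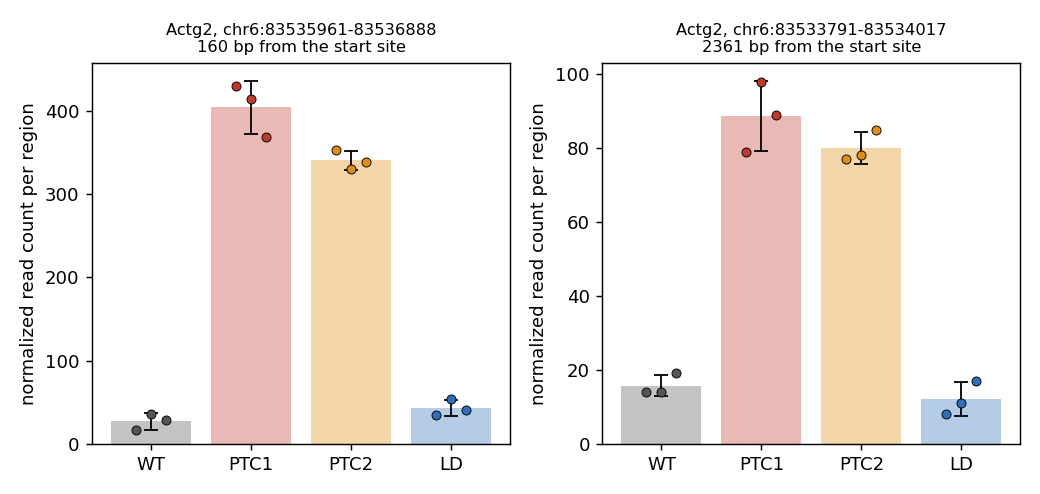
Normalized read counts of the 2 regions annotated to Actg2 in WT, PTC1, PTC2 and LD. Bars give the mean, error bars the SD and dots the 3 libraries of each group; the start site region stands at means of 404.7 and 341 in PTC1 and PTC2 against 27 in WT and 43 in LD.

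At the start site of Actb, which encodes beta-actin, values were slightly lower in all 3 mutants, but the direction in PTC2 and against LD depended on the scaling. The region (chromosome 5, 142905667 to 142907273) had 3331 ± 23.5 in WT, 3033 ± 162 in PTC1, 2980 ± 124 in PTC2 and 2799 ± 156 in LD. The log2 changes were -0.14, -0.16 and -0.25 (adjusted p = 0.0223, 0.00817 and 0.00017), and the PTC2 change was 0.004 after chromosome centring. Against LD the premature stop lines were 0.10 higher at Actb (adjusted p = 0.0426), a call lost under both centrings and in the fit on only the groups compared, with -0.095 under loess normalization (adjusted p = 0.0168). Scaling to the same median ended the Actb call in PTC1 and PTC2, local and chromosome centring ended those of PTC1 and LD, and loess normalization that of LD. The PTC1 call also ended without WT replicate 2 (-0.14, adjusted p = 0.0537), WT replicate 3 (-0.13, 0.0567), PTC1 replicate 1 (-0.13, 0.055) or PTC1 replicate 2 (-0.10, 0.137). The difference of Actb from LD missed the threshold without WT replicate 2, PTC1 replicate 1, PTC1 replicate 3, PTC2 replicate 1, LD replicate 2 or LD replicate 3, at 0.08 to 0.11. A weaker region near Actb (142912806 to 142913053) fell in all 3 mutants, by a log2 change of -0.92 in PTC1, -1.19 in PTC2 and -1.11 in LD.

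The start site region of Acta2, which encodes smooth muscle alpha-actin (chromosome 19, 34254222 to 34256027), had 1537 ± 90.5 in WT, 1650 ± 34 in PTC1, 1908 ± 50.1 in PTC2 and 1717 ± 57 in LD. Its change passed the test in PTC2 (0.31, adjusted p = 2.56e-05) and LD (0.16, adjusted p = 0.0209) and not in PTC1 (0.10, adjusted p = 0.116). Both weaker results moved across the threshold: Acta2 was called in PTC1 under loess normalization, both centrings and without WT replicate 3 (0.15, adjusted p = 0.0466). In LD its call was lost under scaling to the same median, both centrings, and without WT replicate 2 (0.12, adjusted p = 0.132) or LD replicate 3 (0.14, adjusted p = 0.0918). A region 34265495 to 34266122 near Acta2 was higher in all 3 mutants, at 391.7 in WT, 690.3 in PTC1, 1005 in PTC2 and 731.3 in LD. Near Acta1, the skeletal muscle actin gene (chromosome 8), the region at 123883230 to 123883886 went from 471.7 ± 56.7 in WT to 177.3 ± 22.5 in PTC1 and 346 ± 26.7 in PTC2, and stood at 575.3 ± 19.6 in LD. Its log2 changes were -1.41, -0.44 and 0.29. The LD call of that Acta1 region was lost under 3 scalings or centrings and without WT replicate 1 (0.26, adjusted p = 0.0784), WT replicate 2 (0.23, 0.123) or LD replicate 2 (0.26, 0.0793). Near Actc1, the cardiac actin gene (chromosome 2), the region at 114059630 to 114060125 had 105 in WT, 146.3 in PTC1, 46 in PTC2 and 62.67 in LD, with changes of 0.48, -1.17 and -0.73. The PTC1 change near Actc1 lost its call without WT replicate 3 (0.43, adjusted p = 0.0542) or PTC1 replicate 2 (0.44, adjusted p = 0.0542).

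Of the 18 actin family regions, 10 were higher and 5 lower in PTC1, 10 and 5 in PTC2, 8 and 4 in LD, and 9 and 3 in the premature stop lines against LD, with the Actb and Dguok signs depending on the scaling or centring. The counts adjusted over the list alone were the same. In LD the 8 rises became 5 under scaling to the same median and without WT replicate 1 or WT replicate 2, and the 4 falls became 2 under either centring. Against LD the 9 rises became 5 without LD replicate 3, and they include regions near Actc1 and Acta2 (34265495 to 34266122) where the lines lay on opposite sides of LD. No region lay between 120298089 and 120369661 on chromosome 11, a gap of 71572 bp that holds Actg1 (120345687 to 120348495), so the deletion itself could not be checked at its own locus. No region was listed with Acta1, Actc1 or Actg1.

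PTC1 against WT asks what the exon 3 premature stop line does to accessibility. Regions near genes that WT fibroblasts kept nearly closed stood open in PTC1, and others were lost. The start site of Trim68, an E3 ubiquitin ligase gene (chromosome 7, 102686940 to 102687592), rose from 12.33 ± 3.51 to 938.7 ± 98.1 (n = 3; log2 6.17, SE 0.263, limma adjusted p = 4.94e-18). Sox2, a transcription factor of neural and pluripotent cells (chromosome 3, 34649614 to 34651366), rose from 23 ± 5.29 to 1025 ± 71 (log2 5.44, SE 0.211, adjusted p = 5.13e-19). It lay in a stretch of 15 regions (34565342 to 35405708) with a median log2 change of 2.52 in PTC1. Overlapping stretches were lower in PTC2 (median -2.05) and LD (median -3.03). Malrd1 (chromosome 2, 15526230 to 15526873) fell from 319.7 ± 43.7 to 5.333 ± 2.52 (log2 -5.73, adjusted p = 5.42e-21). Piezo2, a mechanically activated ion channel (chromosome 18, 63386087 to 63387439), fell from 901.3 ± 58.6 to 26.33 ± 2.31 (log2 -5.05, adjusted p = 1.22e-25).

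Of the 81985 regions tested, 25096 were higher and 25562 lower in PTC1 (61.8% in all), and 10464 and 9563 of these changed by a log2 of 1 or more. The rule for named regions chose from 4765 rises and 4478 falls. After Trim68, the largest rises were at Ppp1r3c, Pctp, Clec11a, Sox2, Pcdh10, Mlf1, Ccdc114, Gstt3 and Maml3, down to 5.16. The falls ran from Malrd1 through Nol4, Zfp141, the NADPH oxidase gene Nox4, the ephrin receptor gene Epha3, Mlh3, Piezo2, Mga and Ccdc30 to Adgrl3 at -4.71. The order depends on the pseudocount: with 10 in place of 1, Piezo2 (-4.65) was the largest of these falls, and Epha3 and Mlh3 moved to -3.28 and -2.89. Mga, a MAX-binding repressor gene (chromosome 2, 119896863 to 119897673), had 477.7 ± 35.8 in WT, 15 ± 3.61 in PTC1, 7.333 ± 6.43 in PTC2 and 494.3 ± 27.4 in LD. Regions with no listed gene changed by a log2 of 1 or more in 28.2% of cases and regions with a gene in 15.9%.

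In the contractile list (MRTF-SRF targets), 10 of 31 genes rose and 12 fell in PTC1: Cnn1, a smooth muscle calponin, rose by 1.43, and Synpo2 fell by 2.82. Actin-binding and remodelling genes gave 9 rises and 12 falls of 41, with Tmsb10 at 0.52 and Twf2 at -0.50. The actin family gave 1 rise (Actg2) and 1 fall (Actb) of 3 genes. Immediate early genes went both ways, with 8 of 19 higher, such as Klf6 at 0.95, and 6 lower, such as Egr1 at -0.67. YAP-TEAD targets had 3 of 17 higher and 8 lower (camera adjusted p = 0.768), the pathway regulators Wwc1 (-0.86) and Ptpn14 (-0.45) among the lower. Among nonsense-mediated decay genes 8 of 19 rose and 3 fell, with Upf1 at 0.48, while Gspt1 and Etf1 read -0.54 and -0.36 and turned positive after local centring. The mRNA decay machinery had 14 of 29 genes higher, Lsm4 at 0.41 among them, and 4 lower, with Dcp1b at -0.76. COMPASS complexes, which methylate histone H3 lysine 4, had 3 of 16 genes higher and 5 lower, with Kmt2a at -0.51 and Cxxc1 at -0.48 (0.04 after local centring).

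Fibroblast and matrix genes had 10 rises and 16 falls of 41 in PTC1, with the gelatinase gene Mmp2 at 1.54 and Pdgfrb at -0.62. Of 21 p53 targets 9 rose and 4 fell, with Pmaip1 at 1.01 and Plk2 at -0.40 (0.06 after local centring). The antiviral genes Mx2 and Mx1 fell by 2.07 and 3.85, in an interferon list with 7 of 25 genes higher and 12 lower. Mx2 lay in a stretch of 14 regions on chromosome 16 (97475467 to 97717138) with a median log2 change of -2.31 in PTC1. Cell cycle genes split 10 and 10 of 29, with the inhibitor gene Cdkn2b at -1.69 (adjusted p = 2.51e-18). Of 13 housekeeping genes 2 rose and 3 fell, with Tbp at 0.52 and Ywhaz at 0.35 (-0.08 after chromosome centring and -0.04 after local centring). Markers of other cell types moved in both directions. Muscle markers had 2 of 8 higher and 1 lower, with the myogenic factor gene Myf6 at 4.97, and adipocyte markers 3 of 9 higher and 3 lower, with Cebpa at -1.69 and Lpl at 3.30. For cartilage and bone 5 of 8 were higher and 2 lower, with Comp at 0.50 and Spp1 at -0.53. Epithelial markers gave 3 of 8 higher and 0 lower, with Krt14 at 1.10 and Cldn3 at 0.64, and endothelial markers 3 of 7 higher and 1 lower, with Sox18 at -0.99 and Erg at 0.76. For blood, 3 of 7 were higher and 1 lower, with Tal1 at 0.87 and Ptprc at -0.66, and for neural cells 4 of 8 and 2, with Sox2 at 5.44 and the synaptic gene Syt1 at 3.85. The Cldn3 call was lost without WT replicate 3 (0.51), PTC1 replicate 1 (0.61) or PTC1 replicate 3 (0.60). Chromosome centring ended the PTC1 calls of Etf1 (0.11) and Cxxc1 (-0.01) and moved Tmsb10 to 0.32, Twf2 to -0.21, Egr1 to -0.205, Gspt1 to -0.15, Upf1 to 0.31, Lsm4 to 0.24, Kmt2a to -0.22, Pdgfrb to -0.15, Plk2 to -0.23, Tbp to 0.30, Comp to 0.33 and Erg to 1.15. Local centring ended the calls of Tmsb10, Upf1, Lsm4, Kmt2a and Comp and moved Klf6, Sox18 and Ptprc by over 1.5 times.

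Adjusted over the list alone, 12 of the 20 lists gave the same PTC1 counts. The others gave 7 and 12 for actin-binding, 7 and 3 for nonsense-mediated decay, 2 and 5 for COMPASS, 8 and 12 for interferon, 12 and 10 for cell cycle, 1 and 0 for epithelium, 4 and 1 for blood, and 5 and 2 for neural markers. Camera called 0 of the 20 lists in PTC1, with 0 at an unadjusted p under 0.05 and a lowest adjusted p of 0.768, and 0 with an estimated correlation. Median, mean and test did not share a sign for the actin-binding, MRTF-SRF, nonsense-mediated decay, fibroblast, p53, cell cycle, housekeeping and adipocyte lists. Over 12337 genes read at the region nearest the start site, 33.3% were higher and 28.5% lower in PTC1.

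PTC2 against WT asks the same of the exon 5 premature stop line. Some regions open in WT had almost no reads in PTC2, part of them within longer stretches that fell together. Whether copies of the DNA were lost there was not tested. At Gpc6, a cell surface heparan sulfate proteoglycan gene (chromosome 14, 116928289 to 116929110), values fell from 312 ± 49.4 to 1 ± 1 (n = 3; log2 -7.42, SE 0.226, limma adjusted p = 4.32e-21), while PTC1 and LD stood at 863.3 and 536.3. Crlf2, which encodes a cytokine receptor (chromosome 5, 109556822 to 109559084), fell from 3378 ± 175 to 68.67 ± 19.1 (log2 -5.64, adjusted p = 2.36e-25). Hs3st3b1, a heparan sulfate sulfotransferase gene (chromosome 11, 63921867 to 63922749), rose from 20.67 ± 5.51 to 727.3 ± 65.5 (log2 5.10, adjusted p = 5.3e-20) and stood at 486.3 ± 59.5 in PTC1 and 27 ± 4.58 in LD. Trim68 rose to 489.3 ± 28.7 (log2 5.23, adjusted p = 3.03e-16).

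In PTC2, 23276 regions were higher and 24451 lower (58.2%), 7540 and 10998 of them by a log2 of 1 or more. Under scaling to the same median 28425 were higher and 21014 lower, so which direction held more regions depended on the scaling. The other large rises, of 5363 to choose from, were at Wscd2, the kidney stroma factor gene Foxd1, Cacna1h, the matrix gene Postn, Brsk2, Abr, Chsy3 and Gng2, down to 3.69. Of 2696 falls, the largest after Gpc6 were Mga (-6.51), Trav12-2, Crlf2, the protocadherin gene Pcdh9 (-5.12), Kcnt2, Pcdh7, Slitrk6, Ptgr2 and Zfp882 at -4.31. With a pseudocount of 10, Crlf2 (-5.46) came before Mga (-4.89) and Gpc6 (-4.86), Slitrk6 moved to -2.48, and the rises at Postn and Brsk2 to 2.42 and 2.61. Regions without a listed gene changed by a log2 of 1 or more in 26.6% of cases against 13.6% with a gene.

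In the contractile list, 17 of 31 MRTF-SRF targets rose and 2 fell in PTC2, with the smooth muscle genes Lmod1 at 1.88, Cnn1 at 1.43 and Myl9 at 0.83. The list as a whole did not pass: the camera adjusted p was 0.152, and 0.861 with an estimated correlation. YAP-TEAD targets had 10 of 17 genes higher and 0 lower, with Amotl1 at 0.47 and Wwc1 at 0.64 (camera adjusted p = 0.165). In the fibroblast and matrix list 21 of 41 rose and 5 fell, led by Thbs2 (2.74) and Tgfb2 (0.51), with Postn at 4.08. The actin family gave 2 rises (Actg2, Acta2) and 1 fall (Actb, which read 0.004 after chromosome centring) of 3. Actin-binding genes counted 13 higher and 7 lower of 41, with Cap2 at -1.77 and Tmsb10 at 0.35 (-0.06 after local centring). Of 25 interferon response genes 5 rose and 8 fell, the median was -0.13, and camera called the list as lower, the 1 list called in PTC2 (adjusted p = 0.0495). That call was lost with an estimated correlation (adjusted p = 0.713) and with the highest-mean region of each gene (adjusted p = 0.1), while chromosome and local centring gave adjusted p = 0.00619 and 0.00681. Mx2 fell by 1.38, Oasl1 by 2.17 and Mx1 by 3.46, genes induced by interferon in antiviral defence. Mx2 lay in a stretch of 13 regions on chromosome 16 (97285923 to 97637178) with a median log2 change of -1.98 in PTC2.

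Immediate early genes had 8 of 19 higher and 4 lower in PTC2, with Egr3 at -0.96 and Junb at 0.48. Nonsense-mediated decay genes had 6 of 19 higher and 1 lower, with Magohb at 0.49 and Upf3b at -0.37 (0.01 after local centring). In the mRNA decay machinery 16 of 29 rose and 1 fell, with Lsm4 at 0.39 and Edc4 at 0.56. COMPASS genes split 3 and 3 of 16, with Kmt2d at 0.36 and Cxxc1 at -0.27 (0.04 after chromosome centring and 0.10 after local centring). The p53 targets had 8 of 21 higher and 3 lower, with Eda2r at -0.93 and Rrm2b at 0.28 (-0.03 after local centring), and cell cycle genes 8 of 29 higher and 3 lower, with Mcm2 at 0.64 and Cdkn2b at -0.67. Housekeeping genes had 4 of 13 higher and 3 lower, with Ywhaz at 0.30 and Gusb at -0.58. Of the markers of other cells, muscle had 5 of 8 higher and 0 lower (Tnni1 0.84, Des 1.28), adipocytes 0 of 9 higher and 3 lower (Plin4 -0.78, Cebpb -0.23), and cartilage and bone 6 of 8 higher and 1 lower (Spp1 -1.55, Comp 1.03). Epithelial markers had 3 of 8 higher and 2 lower (Krt5 2.26, Cldn4 -1.43), endothelial 2 of 7 higher and 3 lower (Erg 1.06, Tek -1.20), blood 4 of 7 higher and 1 lower (Cd74 1.37, Ptprc -0.66) and neural 1 of 8 higher and 3 lower (Map2 0.48, Tubb3 -0.50). Chromosome centring ended the PTC2 calls of Upf3b (-0.05) and Cebpb (-0.02), the latter also lost under scaling to the same median, and moved Junb to 0.26, Lsm4 to 0.16, Edc4 to 0.33, Kmt2d to 0.20, Eda2r to -0.615, Rrm2b to 0.12 and Ywhaz to 0.145. Local centring ended the calls of Junb, Lsm4, Edc4, Kmt2d, Ywhaz and Cebpb and moved Wwc1, Tgfb2, Mcm2, Cdkn2b, Gusb, Tnni1, Comp and Map2 by over 1.5 times, as loess normalization did Ywhaz and scaling to the same median did Cxxc1.

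The PTC2 counts adjusted over the list alone were the same for 14 of 20 lists, and became 11 and 0 for YAP-TEAD targets, 2 and 3 for COMPASS, 4 and 4 for housekeeping, 6 and 0 for muscle, 4 and 2 for epithelium and 2 and 3 for neural markers. At an unadjusted p under 0.05, camera had 4 lists. The actin-binding, immediate early, p53, cell cycle, housekeeping and epithelial lists had a median, mean and test that did not share a sign. Of all start site regions 37.4% were higher and 16.3% lower in PTC2.

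LD against WT shows what loss of the locus without mutant mRNA goes with. The deletion line had its largest changes at losses. Il1rapl1, a synaptic adhesion gene (chromosome X, 88115554 to 88116282), fell from 180 ± 20.8 to 0.6667 ± 1.15 (n = 3; log2 -6.97, SE 0.284, limma adjusted p = 4.95e-18), with 264 in PTC1 and 120 in PTC2. Gabre, a GABA receptor subunit gene (chromosome X, 72273691 to 72275509), fell from 573.3 ± 46.5 to 20.33 ± 2.08 (log2 -4.75, adjusted p = 1.09e-23). Bmp6, a growth factor gene (chromosome 13, 38348316 to 38348971), rose from 32.67 ± 4.16 to 284.7 ± 22 (log2 3.09, SE 0.193, adjusted p = 9.19e-14).

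Fewer regions were called than in either premature stop line: 18561 higher and 20278 lower (47.4%), of which 5654 and 5283 changed by a log2 of 1 or more. Scaling to the same median gave 15167 higher and 23919 lower. Of 2595 rises, the largest were at Proser2 (3.90), Dnm3, Mss51, Fbxl7, Map3k7cl, Epop, Pnlip, Txlnb, Bmp6 and Ildr1 (2.99). Map3k7cl was also higher in PTC1 (3.17) and PTC2 (2.47). Of 4223 falls, Il1rapl1 was followed by Slitrk6 (-5.14), Fgf14, Gabre, Lmbr1, Trim30a, Ldb2, the p53 target Eda2r, Moxd2 and Ica1 (-3.80). A pseudocount of 10 put Gabre (-4.27) before Il1rapl1 (-4.16) and moved Slitrk6 to -2.63, Trim30a to -2.49, Moxd2 to -1.92, Dnm3 to 2.12, Mss51 to 2.28, Txlnb to 1.87 and Pnlip to 1.53. Slitrk6 was also low in PTC1 (-4.19) and PTC2 (-4.45). Changes by a log2 of 1 or more made up 15.6% of regions without a listed gene and 8.31% of those with a gene.

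Of 19 immediate early genes 10 fell, 1 rose and 8 were not called in LD, with Egr1, a growth response factor, at -0.79, Klf6 at -0.60 and Egr3 at 0.72. As a list they did not pass the test (camera adjusted p = 0.31). Actin-binding genes fell in 14 of 41 cases and rose in 7, including the actin regulators Wasl (-1.0), Pls3 (-1.02), Msn (-0.93) and Diaph1 (-0.77). These lie on chromosomes with low LD medians (6, 18 and X), and after chromosome centring they read -0.64, -0.52, -0.43 and -0.23, each still called. Of 31 MRTF-SRF targets 6 rose and 10 fell, with the focal adhesion gene Zyx at -0.68 and Cald1 at -0.55. Among the rises was Myl9 at 0.66 (0.54 after chromosome centring). The actin family gave 2 rises (Actg2, Acta2) and 1 fall (Actb) of 3. YAP-TEAD targets split 4 and 4 of 17, with Gadd45a at -0.53 and Ankrd1 at 0.80. Nonsense-mediated decay had 1 of 19 genes higher and 3 lower, with the X-linked Upf3b at -1.13 and Etf1 at -0.64, and mRNA decay machinery 6 of 29 higher and 10 lower, with Lsm5 at -0.61 and Dis3l2 at 0.61. COMPASS genes had 2 of 16 higher and 5 lower, with Cxxc1 at -0.86 and Hcfc1, on X, at -0.88 (0.04 after local centring).

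Fibroblast and matrix genes had 16 of 41 higher and 10 lower in LD, with Timp1 at -0.78 and Lox at -0.69. Among p53 targets 3 of 21 rose and 9 fell, and Eda2r fell by 3.84 (adjusted p = 9.59e-23). Interferon genes had 5 of 25 higher and 8 lower, with Usp18 at -0.46, Oasl1 at -1.13 and the RNA sensor gene Ifih1 at 1.29. Mx1, lower in both premature stop lines, was lower in LD too, at -1.94. Cell cycle genes had 6 of 29 higher and 8 lower, with Ccnd3 at 0.96 and Bub1 at 0.35, and housekeeping genes 1 of 13 higher and 5 lower, with Pgk1 at -0.97 and Ywhaz at -0.27. Muscle markers had 2 of 8 higher and 0 lower (Myf6 1.64, Myh3 0.49), adipocyte 3 of 9 higher and 1 lower (Cebpa 0.94, Pparg 1.11), cartilage and bone 2 of 8 higher and 3 lower (Runx2 -0.31, Sox6 0.23). Epithelial markers gave 3 of 8 higher and 2 lower (Krt5 -0.81, Cldn3 0.96), endothelial 3 of 7 higher and 2 lower (Sox18 -0.91, Fli1 2.41), blood 1 of 7 higher and 1 lower (Tal1 0.65, Cd74 -0.56), and neural 1 of 8 higher and 1 lower (Gfap 0.36, Syt1 -0.84). Calls were lost for Myh3 without WT replicate 2 (0.29), LD replicate 2 (0.45) or LD replicate 3 (0.51), for Sox6 without WT replicate 2 (0.18), for Cd74 without LD replicate 3 (-0.38), for Gfap without WT replicate 2 (0.32) or WT replicate 3 (0.28), and for Syt1 without WT replicate 1 (-0.61), WT replicate 2 (-0.75) or LD replicate 3 (-0.65). Chromosome centring ended the LD calls of Etf1 (-0.10), Usp18 (-0.10), Ywhaz (-0.10), Myh3 (0.39), Cd74 (-0.02) and Gfap (0.26). It moved Zyx to -0.32, Cald1 to -0.19, Egr1 to -0.25, Gadd45a to -0.17, Upf3b to -0.64, Lsm5 to -0.24, Hcfc1 to -0.385, Cxxc1 to -0.32, Timp1 to -0.28, Lox to -0.15, Bub1 to 0.23 and Pgk1 to -0.47. Local centring ended the calls of Pls3, Zyx, Cald1, Gadd45a, Lsm5, Timp1, Lox and Cd74, scaling to the same median those of Myh3 and Sox6, and loess normalization those of Myh3 and Ywhaz.

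Adjusted over the list alone, the LD counts were the same for 15 of 20 lists and became 7 and 15 for actin-binding, 6 and 11 for MRTF-SRF, 16 and 11 for fibroblast, 6 and 9 for cell cycle and 4 and 1 for adipocyte genes. Camera called 0 of the 20 lists in LD and had 1 at an unadjusted p under 0.05, the immediate early genes. With an estimated correlation 0 were called (lowest adjusted p = 0.919), and after local centring the immediate early genes were called as lower (adjusted p = 0.0348, with 0.0348 to 0.919 over the alternatives). The YAP-TEAD, nonsense-mediated decay, COMPASS, interferon, cell cycle, cartilage and bone, and epithelial lists had signs that differed between median, mean and test. Among start site regions 16.9% were higher and 29.5% lower in LD.

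**Figure D2:**
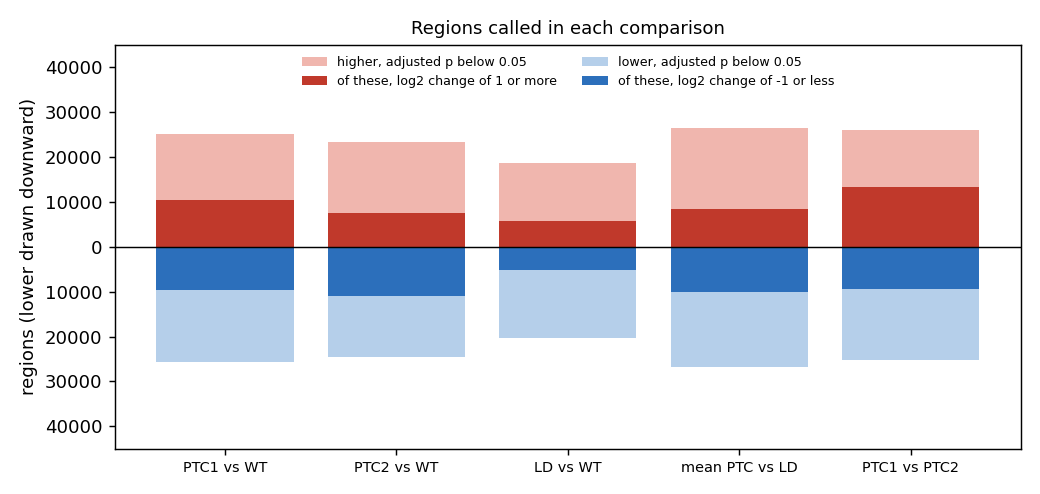
Number of regions called higher or lower in each comparison, out of 81985 tested, with the darker part giving those that changed by a log2 of 1 or more. PTC1 against WT has 25096 higher and 25562 lower regions, PTC2 against WT 23276 and 24451, and LD against WT 18561 and 20278.

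The mean of the premature stop lines against LD is the direct comparison of alleles that make a mutant mRNA with the allele that makes none. Besides Actg2, the premature stop lines exceeded LD at Il1rapl1 (log2 6.95), Trim68 (6.11, limma adjusted p = 1.75e-19), the Wnt receptor gene Fzd3 (4.70), Gabre (4.64), Gng2, Rnls, Prss2, Hs3st3b1 (4.42, adjusted p = 1.94e-20) and Kcnq5 (4.39). They lay below LD at Mga (-5.77), Pcdh9 (-5.36), Rftn1, Mss51, Zfp518b, Pcdh7, the chromatin remodeller gene Chd7 (-3.92), Cnnm1, Gda and Stmn2 (-3.84). With a pseudocount of 10, Il1rapl1 stood at 4.14, behind Trim68 (5.15), Mss51 at -2.56, and Pcdh9 (-4.89) before Mga (-4.64). Il1rapl1 and Gabre had fallen in LD against WT. In all, 26354 regions were higher and 26739 lower (64.8%), of which 8295 and 9975 differed by a log2 of 1 or more, and scaling to the same median gave 31859 higher and 21737 lower. The named regions came from 4493 rises and 1904 falls. That scaling moved the median of all regions by 0.12 in this comparison, to 0.11, and every named region outside the actin family kept its call under it.

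Immediate early genes were higher in the premature stop lines than in LD in 13 of 19 cases and lower in 3, with Klf6 at 1.28, Jund at 0.49 and Egr3 at -1.01. Actin-binding genes counted 18 higher and 9 lower of 41, with Wasl at 1.03 and Tmsb10 at 0.89, and MRTF-SRF targets 14 higher and 6 lower of 31, with Zyx at 0.87 and Cald1 at 0.92. In the actin family 2 of 3 were higher and 0 lower, of which Actb turned to -0.095 under loess normalization. Of 17 YAP-TEAD targets 5 were higher and 4 lower, with Gadd45a at 0.81 and Ankrd1 at -0.63. For nonsense-mediated decay 9 of 19 were higher and 2 lower, with Upf3b at 0.89 and Etf1 at 0.41, and for mRNA decay machinery 16 of 29 and 5, with Lsm5 at 1.03 and Exosc4 at 0.61. COMPASS genes had 6 of 16 higher and 4 lower, with Kdm6a at 0.47 and Hcfc1 at 0.72 (-0.10 after local centring). Fibroblast and matrix genes had 16 of 41 higher and 12 lower, with Timp1 at 0.61 and Col1a2 at 0.56 (-0.25 after local centring). Of 21 p53 targets 14 were higher and 3 lower, with Eda2r at 3.14 and Rrm2b at 0.73.

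In the interferon list 5 of 25 genes were higher and 11 lower than in LD, with Mx2 at -1.22, the ubiquitin-like Isg15 at -1.42 and Ifih1 at -1.94 (camera adjusted p = 0.117). Cell cycle genes gave 14 of 29 higher and 9 lower, with Cdkn2b at -1.21 and Mcm2 at 0.84, and housekeeping genes 8 of 13 higher and 3 lower, with Pgk1 at 0.82 and Ywhaz at 0.60. Muscle markers had 5 of 8 higher and 0 lower (Myf6 1.56, Tnni1 0.42), and adipocyte markers 1 of 9 higher and 5 lower, with the adipogenic factor gene Cebpa at -1.77 and Cebpb at -0.38 (camera adjusted p = 0.127). For cartilage and bone 5 of 8 were higher and 2 lower (Comp 0.66, Runx2 0.52), for epithelium 3 of 8 and 3 (Krt5 1.98, Cldn4 -0.62), for endothelium 2 of 7 and 3 (Erg 0.91, Tek -1.66), for blood 2 of 7 and 1 (Cd74 1.63, Ptprc -0.59) and for neural cells 3 of 8 and 2 (Sox2 2.36, Nes -0.67). The mean hides lines on opposite sides of LD for Myf6 (97 in PTC1, 8.333 in PTC2 and 8.667 in LD), Sox2 (1025, 27.67 and 32.33), Tnni1 (105.3, 289.7 and 131.3) and Cldn4 (91, 32 and 83.67). Chromosome centring ended the calls of Col1a2 (0.06) and Cebpb (-0.06) against LD and moved Wasl to 0.54, Tmsb10 to 0.40, Zyx to 0.38, Cald1 to 0.43, Gadd45a to 0.315, Etf1 to 0.255, Lsm5 to 0.54, Exosc4 to 0.15, Hcfc1 to 0.45, Kdm6a to 0.20, Timp1 to 0.34, Rrm2b to 0.27, Mcm2 to 0.35 and Ywhaz to 0.13. Local centring ended the calls of Tmsb10, Zyx, Kdm6a, Mcm2 and Ptprc and moved Klf6, Jund, Upf3b, Pgk1 and Comp by over 1.5 times, and loess normalization moved Jund, Etf1, Kdm6a and Ywhaz by as much. Adjusted over the list alone, 17 of 20 lists gave the same counts against LD, and the others gave 19 and 10 for actin-binding, 6 and 3 for COMPASS and 16 and 13 for fibroblast genes. Camera called 0 of 20 lists, with 2 at an unadjusted p under 0.05 (interferon and adipocyte), and 0 with an estimated correlation (lowest adjusted p = 0.507). Both lists were called as lower after chromosome centring (adjusted p = 0.0368 each) and local centring (0.0178 for interferon and 0.0428 for adipocyte). Short stretches that moved together, such as those holding Mx2, largely stay in the values after either centring. The YAP-TEAD, COMPASS, fibroblast, cell cycle, epithelial, blood and neural lists had medians, means and tests of mixed sign, and 45.2% of all start site regions were higher and 21.7% lower than in LD.

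The premature stop lines also differed from each other. PTC1 exceeded PTC2 in 25932 regions and lay below it in 25320 (62.5%), with 13228 and 9462 differing by a log2 of 1 or more, and scaling to the same median turned the balance to 22487 and 29715. Against WT both lines were higher in 11154 regions and lower in 12352, where independent calls would give 7125 and 7624. Calls against a shared WT are not independent: in 20 simulated draws of unchanged groups the changes of a pair of lines correlated with r = 0.5 and had a covariance of 0.025, with at most 2 regions called in a comparison and 1 in both. Across regions the measured covariance was 0.34 for PTC1 and PTC2 (r = 0.32), 0.0318 for PTC1 and LD (r = 0.038) and 0.292 for PTC2 and LD (r = 0.39). The excess over the simulated value was 0.315, 0.00664 and 0.267. By r, PTC2 was closer to LD than to PTC1, and the group means gave the same order (0.908 with LD and 0.861 with PTC1). Part of the excess of shared calls may come from the 3 shared WT libraries, and a fit with separate WT libraries for each line was not run.

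Regions that moved the same way in both premature stop lines, with a mean of these lines that differed from LD, were counted. A response to mutant mRNA could be sought in them. Only the mean was tested against LD, so 1 line can lie on the other side of LD. PTC1 did so in the region near Acta2 at 34265495 to 34266122 (690.3 against 731.3 in LD). Actg2 ranked as the sixth of 1929 eligible rises by its smallest change (3.10), with Trim68 (5.23), Hs3st3b1 (4.42), Gng2 (3.15) and Hoxc12 (3.13) among those before it. The Gng2 and Hoxc12 regions lay in stretches of neighbouring regions that rose together in both premature stop lines. Hoxc12, a posterior HOX gene, had 19.67 in WT, 233.3 in PTC1, 180.7 in PTC2 and 18.67 in LD. The developmental factor gene Isl1 followed at 2.58, then Nipsnap1, the muscle caveolin gene Cav3 and the hair keratin gene Krt35 (2.36). Of 740 falls, Mga (-4.93), Pcdh9 (-4.26) and the guanine deaminase gene Gda (-3.90) came first, then Zfp518b, Pcdh7, the glutamate receptor gene Gria3, Zkscan16, Tmem196, Sh3bgrl2 and Usp43 (-2.43). Gda had 445 in WT, 21.67 in PTC1, 22.33 in PTC2 and 323.7 in LD. In all, 17506 regions met the definition, 8150 higher and 9356 lower, with 4256 at a log2 of 1 or more. Scaling to the same median turned this balance, to 9779 higher and 7676 lower. The other pairings, chosen after seeing the data, gave 6486 regions for PTC1 with LD against PTC2 and 11349 for PTC2 with LD against PTC1, with 767 and 2510 at a log2 of 1 or more. Simulated unchanged groups gave at most 0, but they hold no differences between lines. That count therefore cannot show how many regions unrelated differences between lines would share.

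Whole chromosomes and long segments differed in level between the lines. Chromosome 6, which carries Actg2, had a median log2 change of 0.20 in PTC1, 0.08 in PTC2 and -0.35 in LD. Chromosome 15 stood at 0.44, 0.18 and -0.17, chromosome 18 at -0.45, -0.28 and -0.55, and the X chromosome at -0.11, -0.27 and -0.52. The range over chromosomes was 0.896 in PTC1, 0.522 in PTC2 and 0.709 in LD. Within 2000000 bp of Actg2, 179 regions, its start site region not among them, had medians of 0.45, 0.39 and -0.32. After local centring the Actg2 start site region still stood at 3.44, 3.28 and 1.01. The highest of the 179 regions stood at 3.83 in PTC1, 2.67 in PTC2 and 1.21 in LD. In the premature stop lines against LD the highest was 3.68, above the Actg2 start site region at 3.10.

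Distal to Actg1 on chromosome 11, PTC2 lay below WT in 68 of 74 regions. The 74 regions, those with a mean of 50 or more from 120369661 to 121952608, had a median log2 change of -0.65 in PTC2 (quartiles -0.99 and -0.52), 0.21 in PTC1 and 0.11 in LD. On the proximal side, 74 regions from 119090835 had a PTC2 median of -0.11, a step of -0.54 at the edited gene. The step was 0.154 in PTC1 and -0.025 in LD. Of the distal regions 63 were called lower and 3 higher in PTC2, and the step was -0.476, -0.502 and -0.542 in its 3 libraries against the WT mean.

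**Figure D3:**
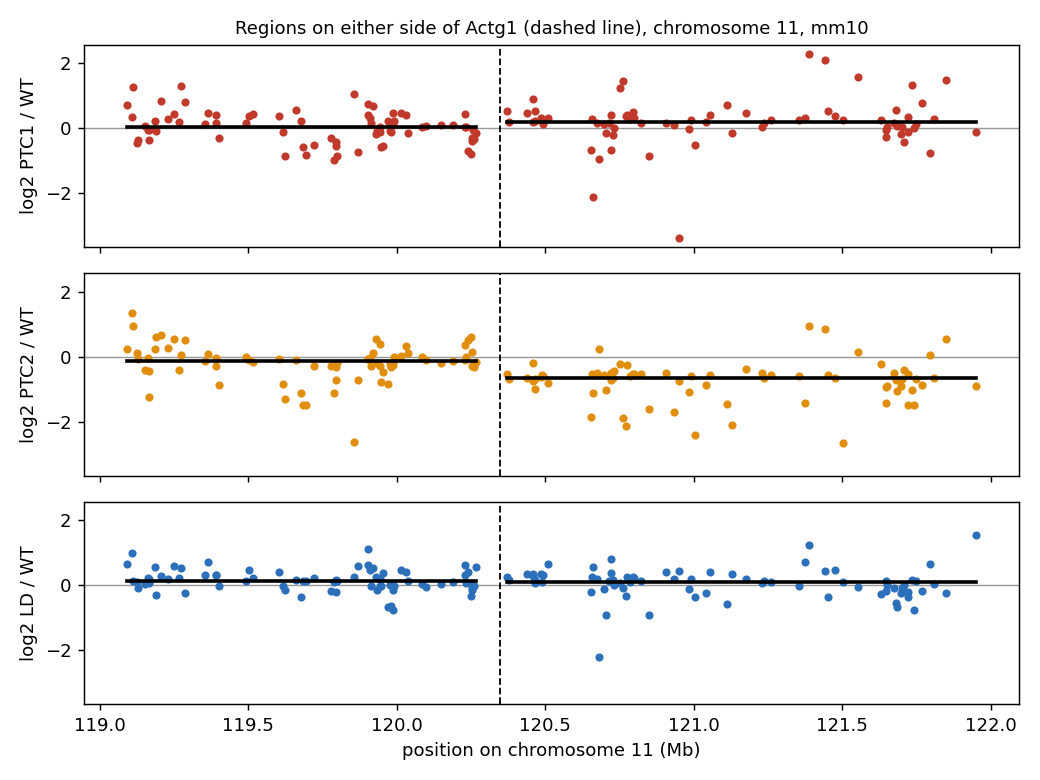
Log2 of the mean normalized read count of each mutant over WT along chromosome 11 around Actg1 (dashed line), 1 point per region, with black lines for the medians of 74 regions on each side. In PTC2 the median steps from -0.11 to -0.65 at Actg1, in PTC1 from 0.06 to 0.21 and in LD from 0.14 to 0.11.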

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

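The tests of copy number, of scaling, of depth and of steps at other boundaries were chosen only after the result was seen. So was the drift test on the number of regions. The tests by other splits of the libraries were set before. The drift test at Actg2 took the measured change of Actg2 as its threshold and used pairings of lines chosen after seeing the data. It was therefore not fixed before the Actg2 result.

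The start site region of Actg2 was 15.2-fold higher in PTC1 and 12.8-fold in PTC2 than in WT, and it was singled out because the premature stop lines differed from LD by a log2 of 3.10 (2.35 after local centring) in a test of that difference. More copies of a long surrounding part of chromosome 6 are argued against, since the smaller of the PTC1 and PTC2 changes was still 3.28 after local centring. A gain confined to a short stretch at Actg2 would stay in the values after that centring and was not tested. Scaling of the samples is argued against as well, since the smallest change under the other scalings was 3.76. Drift between lines that has nothing to do with the alleles remains open: 5 regions rose as much in PTC1 and LD or in PTC2 and LD, against 30 in PTC1 and PTC2. Among start site regions the counts were 0, 0 and 5 for rises and 1, 4 and 5 for falls. The labels name no separate lines of an allele. A response to mutant Actg1 mRNA may account for the rise too, but no second line per allele is named that could part it from drift.

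Distal to Actg1 on chromosome 11, PTC2 had lower values than WT, and the median difference of PTC1 and PTC2 there was 0.92, with PTC1 above WT and PTC2 below in every library; the difference of these medians was not tested. Fewer copies of the segment in the PTC2 line may account for it, since 91.9% of the 74 distal regions lay below WT, with medians of -0.61 for the 40 regions with a gene and -0.75 for the 34 without. Scaling of the samples is argued against by the step of -0.535 between the distal and the proximal median. Whether the step is tied to the edit of Actg1 or is another difference of this line stays open, since 92 of 5736 boundaries scanned over the genome (1.6%) had a step as large in PTC2. The effect of the PTC2 insertion itself on the neighbouring chromatin was not tested.

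Very many regions differed between the lines, 53093 between the premature stop lines and LD and 51252 between PTC1 and PTC2, each by the test of the difference itself. Copy number of whole chromosomes or long segments as the whole cause is argued against, since at least 75.1% of the calls against WT stayed called in the same direction after local centring. That centring subtracts a running median of many neighbouring regions, so gains or losses over shorter stretches largely stay in the values. Copy number changes of that size could account for part of the calls and were not tested. Sequencing depth is argued against, since the highest r between libraries of different groups was 0.933 and the lowest within a group 0.982. Drift between lines could account for much of the count and cannot be told apart from the alleles, since no separate lines of an allele are named. The 51252 regions that differ between both premature stop lines are about as many as those that differ from WT. The alleles themselves stay among the open explanations for part of these regions.

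Other splits of the libraries were too few for a share under 0.05 in the comparisons of 3 with 3, where 1 of the 10 splits, the real one, reached the real value: 50658 regions for PTC1, 47727 for PTC2 and 38839 for LD against WT, and 51252 for PTC1 against PTC2, with a highest other value of 0 in each. For the premature stop lines against LD, 1 of 100 splits reached 53093 and the highest other gave 30622. The many calls of other splits point to a structure of the samples by line. For the regions shared by both premature stop lines and different from LD, 1 of 100 splits reached 17506 and the highest other gave 0. All these splits mix libraries of different lines. That widens the spread within a group and favours the real grouping, so chance is not excluded by them. They do not bear on chance differences between lines.

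The remaining differences between the premature stop lines and LD passed the same test over all 12 libraries and are given as log2 values. Among actin family regions these were 2.77 inside the Actg2 gene body, 1.73 upstream of Actg2, 0.51 near its 3′ end, 0.68 at Dguok, 0.10 at the Actb start site (-0.095 under loess normalization), 0.19 and 0.51 near Acta2, 0.38 near Actc1, and -0.79, -0.23 and -1.22 near Acta1. Near Actc1 PTC1 lay above LD and PTC2 below (146.3, 46 and 62.67 in LD), and at the 0.19 near Acta2 PTC2 lay above and PTC1 below (1005, 690.3 and 731.3 in LD). The 0.19 near Acta2 lost its call without LD replicate 1 (0.16, limma adjusted p = 0.08) or LD replicate 3 (0.18, 0.0559), and the 0.38 near Actc1 without LD replicate 1 (0.37, adjusted p = 0.0649) or LD replicate 3 (0.37, 0.0639). The 0.51 near the 3′ end of Actg2 lost it without LD replicate 3 (0.39, adjusted p = 0.0681), under chromosome centring and, with a turned sign, under local centring (-0.24), as did Dguok under local centring (-0.07). The -0.23 near Acta1 lost it under scaling to the same median, and the Actb value lost it in 6 of the fits that each left out 1 library (0.08 to 0.11). Among the largest positive differences from LD were Il1rapl1 6.95, Trim68 6.11, Fzd3 4.70, Gabre 4.64, Gng2 4.52, Rnls 4.48, Prss2 4.42, Hs3st3b1 4.42 and Kcnq5 4.39. Il1rapl1 and Gabre had fallen in LD against WT, and Prss2 lay in a stretch that had fallen in LD. The largest falls were Mga -5.77, Pcdh9 -5.36, Rftn1 -4.44, Mss51 -4.26, Zfp518b -4.16, Pcdh7 -4.05, Chd7 -3.92, Cnnm1 -3.91, Gda -3.90 and Stmn2 -3.84. Regions shared by PTC1 and PTC2 also differed from LD at Hoxc12 3.44, Isl1 3.38, Nipsnap1 2.56, Cav3 2.60 and Krt35 2.36, and at a second Pcdh7 region -3.65, Gria3 -2.79, Zkscan16 -3.00, Tmem196 -2.51, Sh3bgrl2 -3.51 and Usp43 -2.87.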

How the results depend on the processing

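Local centring, the camera runs after either centring and the other pairings of lines were chosen after seeing the data; the other alternatives were planned. The counts of called regions kept within 1.5 times their value under every alternative except a log2 change of 1 or more. That minimum is stricter by construction and gave 20027 regions for PTC1, 18538 for PTC2, 10937 for LD, 18270 for the premature stop lines against LD, 22690 for PTC1 against PTC2 and 4256 shared regions, and 4, 7, 2 and 4 actin family regions in the first 4 of these. Leaving out 1 library gave 47220 to 51031, 43719 to 47972, 34319 to 39297, 48553 to 53244, 47927 to 51414 and 15901 to 16878 regions. No label says whether replicate numbers mark a day or batch. Residuals of same-numbered libraries correlated with -0.0044 to 0.045 (median 0.014, 18 pairs), others with -0.04 to 0.022 (median -0.0055, 36 pairs). All 12 libraries had their highest mean correlation with their own number, a hint from the data and not the design. A block by number gave 51098, 48182, 39427, 53495, 51688 and 17790 regions. The interferon list in PTC2 (adjusted p = 0.0495) was lost, leaving 0 lists, with an estimated correlation (0.713), the highest-mean region per gene (0.1) and the block (0.0501). Local centring called 1 list in LD, and chromosome and local centring called 2 lists each against LD. Other size factors and tests made for raw counts were not run on the region counts. The variance between replicates was 2.41 to 4.09 times counting noise as a summary per pair of libraries, and by that summary counting depth was not the main limit of precision. The ratio was not taken for regions with low values on their own, so what limited precision there was not tested.

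Some regions changed sign, and the cause was not tested. With each chromosome centred, PTC1 values became -0.002 for Myh9, 0.109 for Etf1, 0.013 for Wdr82, -0.031 for Gtse1, -0.111 for Rrm2b, -0.078 for Ywhaz and 0.013 for B2m. PTC2 became 0.004 at Actb, 0.041 for Cxxc1, 0.116 for Hcfc1 and 0.061 for Pgk1. LD became 0.005 at Dguok and 0.102 for Tead4, and the difference from LD -0.149 for Tead4, 0.06 for Upf2, -0.149 for Magohb and -0.037 for Kmt2d. After local centring, PTC1 was -0.117 at Dguok, -0.086 for Myh9, 0.161 for Gspt1, 0.076 for Etf1, 0.042 for Parn, 0.041 for Cxxc1, 0.045 for Wdr82, 0.063 for Plk2, -0.131 for Rrm2b, 0.104 for Mcm4, -0.041 for Ywhaz and 0.066 for B2m. PTC2 was -0.123 at Dguok, -0.056 for Tmsb10, -0.018 for Myh9, 0.013 for Upf3b, -0.088 for Upf1, 0.098 for Cxxc1, 0.014 for Hcfc1, -0.033 for Rrm2b, -0.09 for Phlda3 and 0.12 for Pgk1. LD was 0.351 for Fhl1, 0.043 for Hcfc1, 0.139 for Kdm6a, 0.095 for Col1a2 and -0.065 for Twist1. The difference from LD was -0.068 at Dguok, -0.236 near the 3′ end of Actg2, -0.097 for Hcfc1, -0.02 for Kmt2d and -0.251 for Col1a2. Under loess normalization the difference from LD at Actb was -0.095.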

Other observations

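The blocks described here, and the shuffles they are set against, were chosen after the data were seen.

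Neighbouring regions often moved together. Among the 60193 regions with a mean of 50 or more, a running median over 11 regions beyond a log2 of 1.2 either way, held for at least 8 regions, gave 106 blocks in PTC1 (45 higher and 61 lower, 1315 regions), 81 in PTC2 (18 and 63, 944 regions) and 38 in LD (5 and 33, 469 regions). The mean is over all 12 libraries, so a region gained in 1 line needs a larger value to enter than a region lost in it, and the numbers of higher and lower blocks cannot be compared. With the regions shuffled, 20 draws gave at most 1, 1 and 0 blocks. The HOXC cluster, whose genes set position along the body axis, was such a block: 15 regions on chromosome 15 from 102890977 to 103146259, holding Hoxc12, Hoxc11, Hoxc8 and Hoxc6, had a median of 30 in WT and 270 in PTC1 (median log2 3.33). In PTC2 11 regions from 102860571 to 102999487 rose from a median of 30 to 87.3. A further PTC1 block on chromosome 15 (71443982 to 71918280, 14 regions) went from 12.2 to 355, and on chromosome 3 13 regions around Maml3, a Notch coactivator gene, went from 44 to 456.

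Losses were also found as blocks, and whether copies of the DNA were lost in them was not tested. In PTC2, 13 regions over T cell receptor alpha V genes on chromosome 14 (53581915 to 53736711) went from a median of 259 to 13.3. On the same chromosome, 14 regions around the protocadherin genes Pcdh20 and Pcdh9 (88429093 to 96761122) went from 138 to 24.7, and 16 regions around Gpc6 and Tgds (115261079 to 118133083) from 102 to 10. In PTC1, 28 regions around Malrd1 and Plxdc2 on chromosome 2 (15526230 to 17368918) went from 225 to 19.8. In LD, 12 regions around Gk and Il1rapl1 on the X chromosome (85775896 to 93070362) went from 119 to 5.33. The median length was 694.5 kb in PTC1, 561 kb in PTC2 and 668 kb in LD.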
